A study of Caenorhabditis elegans with 4 samples.

How the data were processed

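The binding sites of LIN-11, a LIM homeodomain transcription factor of Caenorhabditis elegans known for its roles in vulval cells and some neurons, were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, strain OP62 carried a transgene that makes LIN-11 fused to EGFP and further tags, with a wild-type unc-119 gene as the rescue marker. Hermaphrodites at the second larval stage (L2) were crosslinked with formaldehyde, and tagged protein with its DNA was recovered with a goat antibody against GFP. The general protocol in the labels also speaks of embryos, and the stage label of the libraries, L2, was used here. There were 4 libraries, 2 of ChIP DNA and 2 of input DNA, numbered 1 and 2 in each group.

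The values used were those of 1 combined peak list with 2381 peaks. Per the file headers, its coordinates are on WormBase WS180 and its peaks were called with PeakSeq; the version, the aligner and the filters were not given in the sources used here. PeakSeq compares tags from ChIP DNA with tags from input DNA in each candidate region. Each peak carries a start, an end and 1 q-value deposited by the authors, and q-values in the list stop below 0.01. The q-value is the authors' own value and was used to describe, rank or filter peaks within this list. The list holds no tag count, no fold enrichment and no library total, so the depth of each library is unknown, and no value belongs to a single replicate. Agreement of the replicates therefore could not be measured, and intervals given here cover counting error over peaks, not variation between cultures. A peak list from the 2 inputs or from an untagged strain was not analysed here.

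Chromosome lengths of WS180 were not used here, so the end of the last peak of a chromosome served as its extent. Peaks on each of the 6 chromosomes were compared with the chromosome's share of the summed extent by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over chromosomes, and densities were given with exact Poisson 95% intervals. Each autosome was divided into 3 segments of equal length, and the share of peak midpoints in the central segments was compared with 10000 random placements of the midpoints within their chromosome. The share of peaks with another peak midpoint within 2 kb was compared with random placements in the same way. These placement tests are two-sided, and the smallest p they can give is 1e-04. They draw new positions at random with equal chance along the extent, without regard to genes or mappability. A p from random placement is called a permutation p here. Peak width was correlated with minus log10 of the q-value with 100000 permutations, for which the smallest p is 1e-05. The tests named so far were fixed before the data were examined. Tests of clustering by chromosome, of left against right segments, of the best 10% of peaks by chromosome, of gaps by size, of 100 kb windows, of the longest gap and of clustered against isolated peaks were chosen after seeing the data, each with Benjamini-Hochberg adjustment over its family where it had several members. The tests of 100 kb windows and of the longest gap by chromosome were one-sided, for fuller windows or longer gaps than placed. All these tests treat peaks as independent, which neighbouring peaks are not.

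Tests that need genes or sequence were planned and were not run: peaks near transcript starts, annotation classes, occupancy of fixed gene lists, and the homeodomain core sequence. The gene table used for reference was of assembly WBcel235, which differs from WS180, and coordinates were not converted between builds. No gene is therefore assigned to a peak. The fixed rule for naming items falls back, in that case, to the 20 peaks with the lowest q-values, named by position. Peaks outside this rule, such as the widest peak, those at the densest windows and those given in the closing section, were singled out after their values were seen.

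For the closing section, whole tag numbers were sought for each peak as an inference from the authors' q-values. The product of a q-value and its line number, divided by a number of tested regions, was compared with the upper tail of a binomial distribution with equal chances for ChIP and input, over up to 2500 tags in all and with a relative tolerance of 1e-11. These tag numbers are not values of the list and are used only in the closing section.

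The chromosome, centre and clustering tests were tested on simulated data, in sets of 100 lists of 2381 peaks with 500 placements each. In lists with no effect, 0, 2 and 2 lists passed the threshold of 0.05 in the chromosome, centre and clustering tests. For the chromosome test only the adjusted p of chromosome I was counted, so false calls on the other chromosomes were not measured. With a planted effect of each kind, all 100 lists passed the matching test. From q-values made from known tag numbers, 99.96% of the 2381 pairs of tag numbers were recovered. Those q-values were made with the same formula, at another number of regions. The recovery therefore tests the back-calculation only, not whether the authors' q-values follow the formula.

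Alternatives were a list restricted to the lowest q-values, removal of the widest 10% of peaks, merging of peaks with gaps under 1 kb, a centre of 50% of each autosome, a clustering distance of 5 kb, and a list without the 5% highest scores. Alternatives added after seeing the data were removal of peaks narrower than 50 bp, removal of chromosome I, an extent scaled up by the peak number, placement within 1 Mb bins and placement within segments. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with the random seed set to 1.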

Results

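The list described the regions of the genome recovered with LIN-11::EGFP from L2 hermaphrodites, over both ChIP libraries and both input libraries combined. The question was where in the genome the tagged protein was bound at this stage. The study has no second condition, so the comparisons made were between chromosomes, between parts of chromosomes and between peaks. Library depth is unknown, and no peak has a value per replicate.

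The list held 2381 peaks called for LIN-11::EGFP on the 5 autosomes and X, at 23.9 peaks per Mb. The peaks covered 1.27 Mb, or 1.27% of the 99.7 Mb spanned. The q-values, as the authors gave them, ran from 6.93e-72 to 0.00994 with a median of 0.000334. Of the peaks, 267 had a q-value below 1e-10 and 738 below 1e-05, and 983 peaks (41.3%) had one above 0.001. The median width was 400 bp, with quartiles of 283 and 651 bp, and 242 peaks were at least 1000 bp wide. At the other end, 95 peaks were narrower than 50 bp, and 4 were of 1 bp. The lowest q-value among the 39 peaks of at most 10 bp was 0.000615, above the median of the list.

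Chromosome I, which as background also carries the endogenous lin-11 gene, held more peaks per Mb than any other chromosome. Its 575 peaks gave 38.5 per Mb (exact Poisson 95% interval 35.4 to 41.7), 1.81 times the density of the other chromosomes together. The adjusted p of the exact binomial test was 8.22e-31. Chromosome III followed with 370 peaks and 26.9 per Mb (24.2 to 29.7), a ratio of 1.15 with an adjusted p of 0.0193 in the exact test. Chromosome II had 397 peaks and 26 per Mb (23.5 to 28.7), and its ratio of 1.11 did not pass in the exact test (adjusted p = 0.0685). The exact test treats peaks as independent, and peaks clustered (below). Its p-values may be too small, which matters most near the threshold, as for chromosome III.

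Chromosomes V, IV and X held fewer peaks for their extent. Chromosome V had the lowest density, 346 peaks or 16.6 per Mb (14.9 to 18.4), which was 0.644 times that of the others (exact binomial adjusted p = 6.18e-15). Chromosome IV had 328 peaks and 19 per Mb (17 to 21.1), a ratio of 0.762 with an exact adjusted p of 5.50e-06. The X chromosome had 365 peaks and 20.7 per Mb (18.6 to 22.9), a ratio of 0.843 with an exact adjusted p of 0.00392. Chromosomes II and X changed sides of the threshold when chromosome I was left out of the comparison. The ratio of X was then 0.965 (exact adjusted p = 0.562) and that of chromosome II was 1.28 (exact adjusted p = 2.97e-05). Among the 1190 peaks with the lowest q-values the ratio of chromosome II was 0.986, below 1. The covered share of the extent ran from 0.948% on chromosome V to 1.90% on chromosome I.

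**Figure D1:**
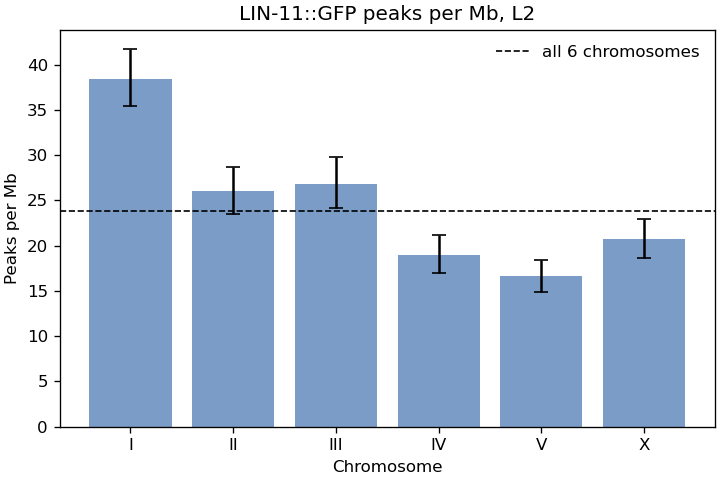
Peaks per Mb of chromosome extent (vertical axis) for each of the 6 chromosomes; bars are the densities, error bars are exact Poisson 95% intervals for counting error, and the dashed line is the density over all chromosomes, 23.9 per Mb. Chromosome I stands at 38.5 per Mb and chromosome V at 16.6.

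The higher density of chromosome I ran along the whole chromosome. Its 14 full bins of 1 Mb held 26 to 50 peaks each, with a median of 39.5. The median full bin held 25 peaks on chromosomes II and III, 22 on X, 18 on IV and 15 on V, and the fullest of them, on II, held 45. Within chromosomes, peaks were uneven on II and IV. The right segment of chromosome II held 185 peaks and the left segment 93, a ratio of 1.99 (exact binomial adjusted p = 2.19e-07). On chromosome IV the left segment held 150 peaks and the right 87, a ratio of 1.72 (exact adjusted p = 0.000154). In the list of 1190 peaks the chromosome IV ratio was 1.31 and no longer passed the exact test (adjusted p = 0.342).

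Autosome centres, which as background are richer in genes than the repeat-rich arms, held no detectable excess or deficit of peaks. The central segments held 653 of the 2016 autosomal peaks, or 32.4%. Random placement gave 33.3% (95% range 31.3 to 35.4%, permutation p = 0.368). By autosome the central share ran from 27.7% on IV to 37.6% on V. In exact binomial tests by chromosome, which were not planned, no autosome passed (lowest adjusted p = 0.12, on IV).

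**Figure D2:**
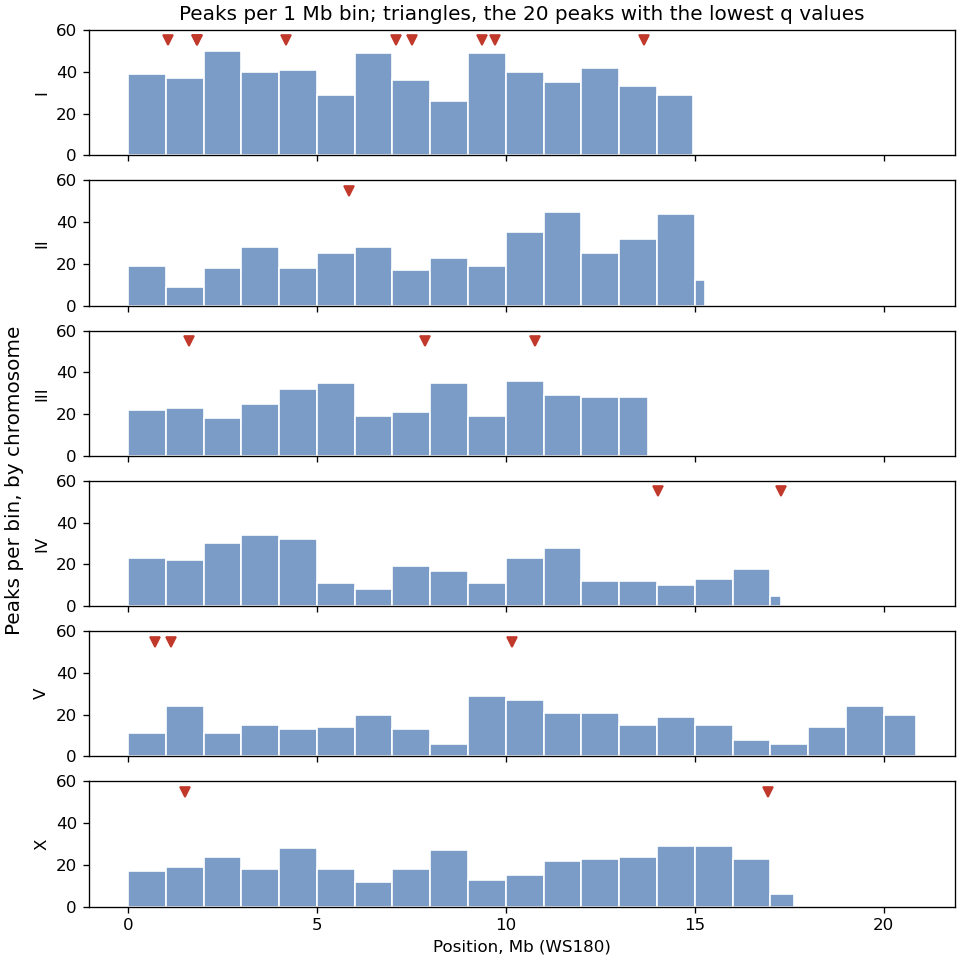
Number of peaks in each 1 Mb bin (vertical axis) along the 6 chromosomes (horizontal axis, WS180 position in Mb); triangles mark the 20 peaks with the lowest q-values, and the last bin of each chromosome is shorter than 1 Mb. Full bins of chromosome I hold 26 to 50 peaks, and peaks are more frequent at the right of chromosome II and at the left of chromosome IV.

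Peaks lay closer together than randomly placed ones. Of the 2381 peaks, 368 (15.5%) had another within 2 kb, midpoint to midpoint, against 9.81% in random placements (95% range 8.19 to 11.5%). The ratio was 1.58, with the smallest permutation p possible, 1e-04. Placing peaks only within their own 1 Mb bin gave 10.3%, also with the smallest permutation p, 1e-04. By chromosome the share was 23.7% on I against 14.2% placed (permutation adjusted p = 0.0003) and 15.9% on V against 6.42% placed (permutation adjusted p = 0.0003). Chromosome IV had 12.5% against 7.33% (permutation adjusted p = 0.0218) and chromosome II had 14.6% against 9.88% (permutation adjusted p = 0.0364). On chromosome III, with 12.4% against 10.2%, and X, with 8.77% against 7.94%, the permutation test did not pass (adjusted p = 0.379 and 0.671). Among the 1190 peaks with the lowest q-values, the permutation test passed over all chromosomes, with 7.82% against 5.14% (p = 0.0032). It no longer passed there on chromosome I (9.84% against 7.79%, permutation adjusted p = 0.565), on II (4.44% against 4.60%, permutation adjusted p = 1) or on IV (4.73% against 3.81%, permutation adjusted p = 0.913). Chromosome II also did not pass the permutation test without the widest 10% of peaks (adjusted p = 0.416). At a distance of 5 kb, III and X passed too (permutation adjusted p = 0.0242 and 0.0314). Differences between chromosomes in clustering were not tested. With peaks less than 1 kb apart merged into 1 region, the share fell to 3.62% against 9.05% placed, because merging removes the close neighbours.

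In the full list, an excess of close neighbours was seen in each gap class up to 5 kb. Gaps of 200 to 1000 bp between neighbouring peaks numbered 171, against 48.0 in random placements, a ratio of 3.56 (permutation adjusted p = 0.000133). Gaps of 1000 to 2000 bp numbered 111 against 58.4, a ratio of 1.90, and gaps of 2000 to 5000 bp numbered 241 against 166, a ratio of 1.45. Each had a permutation adjusted p of 0.000133. Gaps of 5000 to 10000 bp numbered 231 against 247 (permutation adjusted p = 0.279). The total number of gaps is fixed, so more short gaps leave fewer long ones. The last class therefore does not show where the excess ends. In the list of 1190 peaks, gaps of 1000 to 2000 bp were 1.38 times as frequent as placed and no longer passed (permutation adjusted p = 0.146). In the same list, gaps of 5000 to 10000 bp were 1.27 times as frequent as placed (permutation adjusted p = 0.026). No gap was shorter than 200 bp. Clustered and isolated peaks had median minus log10 q-values of 3.43 and 3.48, a difference that did not pass (permutation p = 0.719). Clustered peaks had a median width of 428.5 bp and isolated peaks 394 bp (permutation p = 0.0453), which did not pass when adjusted over both tests (adjusted permutation p = 0.0905). This difference of 34.5 bp depended on the peaks used. It was 187 bp in the list of 1190 peaks (permutation adjusted p = 0.0004) and 44.5 bp when peaks within 5 kb counted as clustered (permutation adjusted p = 0.0006). It was 27 bp without peaks under 50 bp (permutation adjusted p = 0.237), 2 bp without the widest 10% (permutation adjusted p = 0.912) and -90.5 bp with merged peaks (permutation adjusted p = 0.038).

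**Figure D3:**
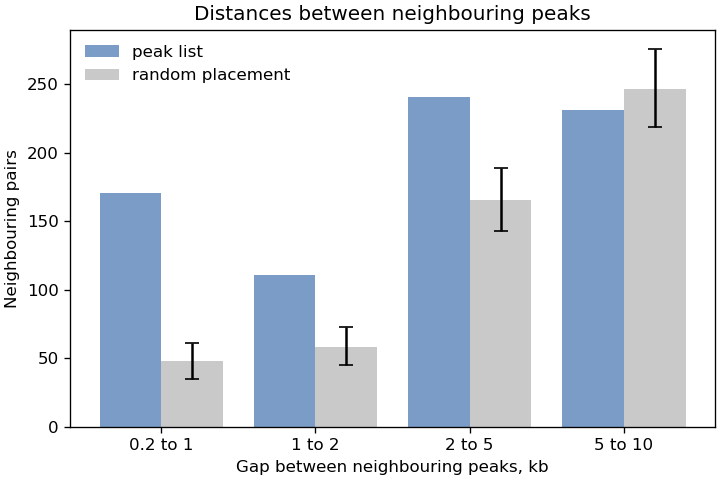
Number of neighbouring peak pairs (vertical axis) by the gap between them in kb (horizontal axis); blue bars are the peak list, grey bars the mean of random placements, and error bars the 95% range of the placements. The list holds 171 pairs 0.2 to 1 kb apart against 48.0 placed, and 231 pairs 5 to 10 kb apart against 247 placed.

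At the finer scale, the fullest 100 kb windows were both on chromosome I, at 6.7 to 6.8 Mb and at 11.5 to 11.6 Mb, with 12 peaks each. Random placements on that chromosome had a median of 10 peaks in their fullest window, and the one-sided permutation test did not pass (adjusted p = 0.183). The longest stretch without a peak lay on chromosome II from 1506102 to 2058966, or 552865 bp. Measured between midpoints it was 553 kb, against a median longest gap of 243 kb in random placements (one-sided permutation adjusted p = 0.0018). Placement within the same segment of the chromosome gave 280 kb (permutation p = 0.0028). In the list of 1190 peaks the longest gap was on chromosome V, 1232 kb, followed by II with 825 kb. Both passed the one-sided test (permutation adjusted p = 0.0255). Without peaks under 50 bp the longest gap of chromosome I, 295 kb, passed the one-sided test too (permutation adjusted p = 0.0255). Two-sided versions of these tests by chromosome were not run.

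The 20 peaks with the lowest q-values were spread over all chromosomes, with 9 on I, 3 each on III and V, 2 each on IV and X, and 1 on II. They were broad, 404 to 5149 bp with a median of 1214.5 bp, and 12 of them were at least 1000 bp wide. The lowest q-value, 6.93e-72, belonged to a 2621 bp peak on X at 16929352 to 16931972. Next came chromosome I at 9379873 to 9382090 with a q-value of 4.85e-67, and chromosome V at 723804 to 728237 with 1.45e-63. Chromosome I at 1067739 to 1070509 had a q-value of 4.82e-42, and X at 1503629 to 1505187 one of 6.87e-42. A pair of neighbours on chromosome I, at 1834996 to 1836022 and 1836245 to 1837476, had q-values of 1.17e-40 and 2.20e-38 and were 222 bp apart. The top 10 also held chromosome IV at 17278188 to 17282068 (7.79e-40), the last peak of its chromosome. It was completed by chromosome III at 10758932 to 10760128 (8.34e-38) and chromosome I at 7078887 to 7084035 (1.32e-36), the latter 5149 bp wide. The other 10 had q-values up to 3.79e-30. Genes at these positions are not given, for want of annotation on the same build.

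Among the best 10% of peaks, 238 in number, chromosome I held 71 peaks, or 29.8% against 24.2% of the whole list. The odds ratio was 1.38 and did not pass Fisher's exact test (adjusted p = 0.113). Chromosome V held 22 of them, 9.24% against 14.5%, with an odds ratio of 0.572 (Fisher's exact adjusted p = 0.0899). Without the widest 10% of peaks the odds ratio of chromosome V was 0.502 and passed the exact test (adjusted p = 0.0398).

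Peaks with lower q-values were wider. Across the 2381 peaks, minus log10 of the q-value and the width had a Pearson r of 0.426 and a Spearman rho of 0.494, each with the smallest permutation p possible, 1e-05. Peaks are not independent replicates, so these values describe this list. PeakSeq computes the q-value from the tags within a region, so it is not independent of the width. The median width was 704 bp in the 239 peaks with the lowest q-values and 250 bp in the 238 with the highest. The widest peak did not follow this order. It spanned 5646 bp on X at 6738549 to 6744194 and ranked 891 with a q-value of 4.54e-05.

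**Figure D4:**
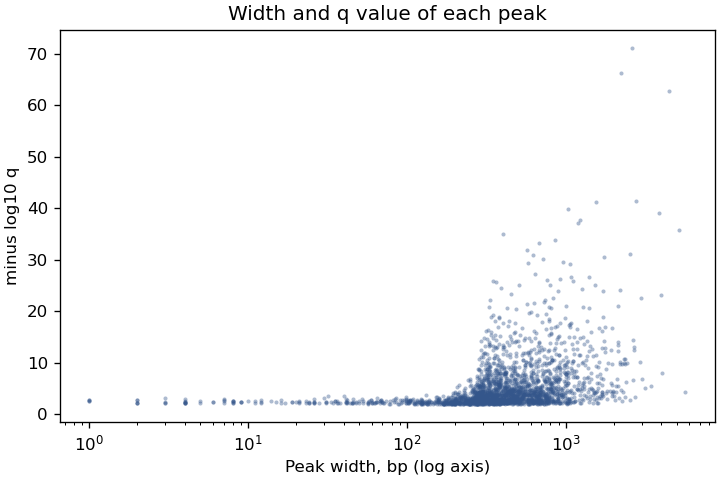
Minus log10 of the q-value (vertical axis) against peak width in bp (horizontal axis, logarithmic) for the 2381 peaks, each a point. Peaks of at most 10 bp all have q-values of 0.000615 or higher, and the 20 peaks with the lowest q-values are 404 to 5149 bp wide.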

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

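The alternatives named in the methods as added, and every alternative of the tests by segment, best 10%, window, gap, clustered peaks and clustering by chromosome, were chosen only after the results were seen. Of 209 alternative values of 46 results, 172 kept their direction and side of the threshold or, for the number of chromosomes past it (5), stayed between 4 and 6. The density ratio of chromosome I passed the exact binomial test under each alternative run, from 1.73 (merged peaks) to 1.96 (the 1190 lowest q-values). The correlation of score and width stayed positive, with a Spearman rho from 0.271 to 0.465. Of the others, 22 turned direction, 9 entered their test and 6 left it. The share in autosome centres, past no threshold, turned from below to above placement in the list of 1190 (34.0%) and with the wider centre (50.1%). In the list of 1190, turns were also seen for the density ratio of chromosome II (0.986), clustering on II (4.44%), gaps of 5000 to 10000 bp (1.27), the clustered minus isolated score difference (0.042), and the best 10% odds ratios of III (0.865), IV (0.719) and X (1.31). That score difference was 0.231 at 5 kb. Merging turned clustering below placement overall (3.62%) and on I (6.96%), II (2.73%), III (1.74%), IV (3.83%), V (2.52%) and X (2.27%), by construction, since merging removes close neighbours. It also turned gaps of 5000 to 10000 bp (1.08), the width difference of clustered peaks (-90.5 bp) and the odds ratio of IV (0.947). That odds ratio was 0.975 without peaks under 50 bp, and that of II was 1.21 without the widest 10%. Chromosome II entered the exact density test without peaks under 50 bp (1.12) and without chromosome I (1.28), and X left it without chromosome I (0.965). Apart from merged clustering, the cause was not tested. Alternatives for transcript starts, annotation classes, gene lists and the homeodomain core were not run, because their main tests were not. Merging gave no value for score against width. No paired analysis was possible because the only list combines the replicates, and its columns carry no replicate number, which also ruled out leaving out a replicate. Unknown depth limits statements on missing peaks: a stretch without peaks is one where none was detected.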

Other observations

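The tests on tag numbers and ratios, on the dense stretch and read numbers of chromosome I, on high input and on split regions among close peaks were chosen only after the result they bear on was seen. No group of the design separates any of the patterns below, so no biological explanation was tested.

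The q-values themselves held more than a rank. The hypothesis was that each q value is a binomial tail of 2 whole tag numbers times 1 number of tested regions, divided by the line number, with the tags being those of ChIP and input. With 20869 regions, 100.0% of the 2381 q-values matched a pair of whole numbers within the tolerance, and with 20868 or 20870 regions 0 matched. The q-values may thus carry the tag numbers of each peak, and 3 peaks with more than 1 possible pair were left out. The values below are inferences of this kind, input tags would be those after the caller's scaling, and their intervals cover counting error only.

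On that reading, enrichment over input was mostly modest. The median peak of the 2378 had 101 ChIP tags (range 15 to 1210) against 46 input tags (1 to 875), and the median ratio of ChIP to input was 2.30, with quartiles of 1.89 and 3.00. In 763 peaks (32.1%) the ratio was under 2, and in 162 it was 5 or more. Of these 162, 11 had a width of at least 50 bp and at least 10 input tags. The peaks of at most 10 bp, 38 with a single solution, had 15 to 20 ChIP tags and 1 to 4 input tags. Median ratios by chromosome ran from 2.11 on X to 2.48 on chromosome I, and clustered and isolated peaks had 2.27 and 2.30 (permutation p = 0.643).

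Ranking by q-value and ranking by enrichment placed different peaks first. On the same reading a q-value depends on the number of tags as well as on their ratio, so a difference between the rankings follows in part from the formula. The same holds for the correlation of q-value and width in the report, and for the Spearman rho of minus log10 of the q-value with the summed tags (0.610) and with the ratio of ChIP to input (0.077). The 20 peaks with the lowest q-values had ratios of 1.92 to 4.85. Among the 2095 peaks of at least 50 bp with at least 10 input tags, the 20 with the highest ratios had 4.50 to 6.41, and the lists shared 1 peak, on chromosome III at 7854416 to 7854819. The highest ratio in that set was at chromosome I, 2639636 to 2639983, with 186 ChIP and 29 input tags and a ratio of 6.41 (95% interval 4.32 to 9.84). Ranked by ratio, chromosome I at 1598408 to 1598808 came next with 6.25 (3.67 to 11.4). These peaks were picked as the highest of 2095 ratios, which the intervals do not allow for. The last of the 20 had an interval of 2.38 to 9.24, which overlaps theirs, so the order by ratio is not resolved.

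The first pattern weighed was the higher peak density of chromosome I. A single dense stretch of up to 7 Mb was argued against by the bin counts in the report. Each full bin of chromosome I held at least 26 peaks, against 21.3 per Mb on the other chromosomes. Without any 1 run of 7 neighbouring 1 Mb bins the ratio was at least 1.71 (95% interval 1.51 to 1.94). That ratio follows from the same bin counts, so it adds no separate support. Regions split by the caller were argued against as the whole cause by the ratio of 1.73 with merged peaks (exact binomial adjusted p = 1.79e-24). More reads over the chromosome, or a lower scaling of its input, stay open: inferred input tags per kb in peaks of at least 300 bp were 0.849 times those of the other chromosomes (bootstrap 95% interval 0.807 to 0.907), which decides nothing, because input was seen only inside regions called for their excess of ChIP over it. Gene density, base composition and mappability also stay open, as untested, and so does a difference in LIN-11 binding.

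The second pattern was the closeness of neighbouring peaks. A candidate explanation is that the caller split single regions, which would place the excess at gaps below 1000 bp. Gaps of 1000 to 2000 bp were 1.90 times and gaps of 2000 to 5000 bp 1.45 times as frequent as in random placements, which argues against splitting at short gaps as the whole cause. The wider of these excesses was also seen among the 1190 peaks with the lowest q-values (1.85), where the 1000 to 2000 bp excess did not pass the permutation test (1.38, adjusted p = 0.146). The 3.56-fold excess below 1000 bp may still include split regions, and clusters of genes or of binding sites were not tested.

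The third pattern was high inferred input, highest among the 242 peaks of at least 1000 bp at chromosome I, 10233718 to 10235964, with 310 input tags per kb against a median of 113. It did not stand apart, since peaks on III at 8416938 to 8417991 (298 per kb), X at 4222324 to 4223400 (276), IV at 10821362 to 10822378 (257) and I at 7474717 to 7475721 (247) followed closely. For the first, a candidate explanation is extra copies of the surrounding DNA, which would raise input beyond the peak. Its 3 neighbouring peaks of at least 300 bp within 20 kb had a mean of 169 input tags per kb. That mean lay at percentile 97.7 of 386 runs of as many such peaks on the chromosome. The runs were not limited to 20 kb, so they were not matched to the neighbours in spacing. The same test, run for the other 4 afterwards, gave percentiles of 55.3 on III (1 neighbour), 47.3 on X (1) and 71.8 on I (2), and the peak on IV had no neighbour in range. With so few neighbours and the first peak picked as the highest, chance stays open, and repeated sequence or open chromatin in the input was not tested. The transgene of the strain carries lin-11 DNA, a possible source of extra copies, and lin-11 lies on chromosome I. Whether these peaks fall on DNA of the transgene was not tested, since no gene is assigned to a position.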
